A study of Mus musculus with 24 samples.

How the data were processed

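Poly-adenylated RNA from the gastrocnemius muscle of 24 male C57BL/6J mice was sequenced, 1 library per mouse, in 3 groups of 8. Per the labels' protocols, RNA was extracted with TRIzol and a column kit, and libraries were made with a kit that captures poly-adenylated RNA; whether the libraries keep strand is not given in the sources used here. The deposited values are TPM, a share of the library's total per gene corrected for transcript length, with 1 table of 55487 Ensembl mouse genes for each library. Per the submitters' processing notes, FastQC, STAR, RSEM and DESeq2 were used with the genome build GRCm38.p6, and no versions or gene annotation release are named there. Each column of TPM has a fixed total, so the depth of the libraries is unknown, and no counting interval or detection floor can be given.

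The design fixed before the data were examined had assumed read counts and a count model. Because the values are TPM, the test used in its place was limma's moderated linear model with a mean-variance trend (limma 3.58.1 in R 4.3.3) on log2(scaled TPM + 1). All log2 fold changes are on this scale, which understates the change of low genes. TPM were scaled between libraries by a trimmed mean of log ratios without weights (30% of ratios and 5% of mean levels trimmed at each end), computed here from the TPM. Genes with a TPM of at least 0.5 in at least 8 libraries were tested, 14690 in all. All 24 libraries entered 1 fit of 3 group means, without covariates, and p-values were adjusted by the Benjamini-Hochberg method within each of 3 comparisons, with a threshold of 0.05 and no fold minimum. Tests were two-sided. Values are given as mean ± SD of scaled TPM over the 8 libraries of a group, and log2 fold changes with the standard error from limma.

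Scaling matters here, because TPM are shares of a total. On the deposited TPM without further scaling, the median gene was 0.39 higher (log2) in the casted than in the uncasted libraries and 0.34 higher in the casted libraries with MOTS-c than in the uncasted ones, while MOTS-c against casting alone gave a median of -0.07. Directions below are relative to the scaled values, that is, to the middle of the distribution of all genes.

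Symbols and coordinates come from a GENCODE annotation of the same genome build, GRCm38, and 55141 of the gene identifiers received a symbol. Coordinates are 1-based. Transcripts of nuclear genes were aligned to the annotated transcripts of mitochondrial genes (blastn 2.17.0). Genes with 90% identity or more over at least 80% of the transcript length were called near-copies of mitochondrial genes, and 16 were found. How the authors' counting divided reads between such copies is not given in the sources used here, so values of these genes, of Amd1 and Amd2, of the alpha-globin genes and of ribosomal protein genes with pseudogenes are uncertain.

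Before the data were examined, 37 gene lists with 749 members were written from general knowledge of muscle disuse, of MOTS-c and of other cell types in muscle, and 715 members were tested. Lists with at least 5 tested members were tested with camera from limma with an inter-gene correlation preset at 0.01, adjusted over the 36 lists tested. The lists were also tested with an estimated correlation and with fry. The rule for named genes took, for casting and for MOTS-c, the 6 largest rises and 6 largest falls past the threshold with a mean of at least 1 and no predicted-gene symbol (all genes that passed, where fewer than 12 did). It also took up to 3 leading members, and the strongest member against the direction, of each list past the threshold, and 18 genes fixed in advance; 2 of the genes this rule took are not reported here. Single measures per library, such as a share or a list mean, were compared between 2 groups of 8 by exact permutation tests over all splits.

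A casting score was the mean log2 value of the 100 genes of smallest p that rose with casting minus that of the 100 that fell. In the planned form, genes were chosen from the uncasted libraries and casted replicates 1 to 4, and MOTS-c libraries were compared with casted replicates 5 to 8 by an exact permutation test over 495 splits, then with these sets of replicates exchanged. The fold changes of casting and of MOTS-c share the casted libraries with opposite sign, so their correlation was compared with 100 simulations with no effect, and recomputed with the casted libraries divided between both comparisons.

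The model was tested on simulated data for 14690 genes with 200 genes changed. For casting, it recovered 49 of 100 genes changed 1.5-fold and 82 of 100 changed 2-fold, with 6 false calls. For MOTS-c it recovered 64 and 81 of 100, with 3 false calls. The simulated noise was independent between genes and libraries, with the same spread in all groups. The real libraries differ from that, and an arbitrary split of casted and MOTS-c libraries gave up to 283 calls in the 3-group fit. Neither the numbers recovered nor the low numbers of false calls therefore carry over to the real data. A simulated scaling difference of 0.476 between groups was recovered as 0.474. Alternatives tried were another scaling (median of ratios), the deposited TPM without scaling, other filters and pseudocounts, a fit of only 2 groups, the replicate number as a block, a test against a fold of 1.2, a residual component as covariate, removal of mitochondrial genes, leaving out each library, and fits with only casted replicates 1 to 4 or 5 to 8. Count models and surrogate variables for counts were planned and not run, since no counts were used here. Figures were drawn with matplotlib 3.10.9.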

Results

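The gastrocnemius, a calf muscle of mixed but mostly fast fibres, was profiled by RNA sequencing in 24 male mice. Both hindlimbs of 16 mice were held in casts for 8 days, and 8 mice were not casted. Of the casted mice, 8 received MOTS-c, a peptide encoded by a short reading frame within the mitochondrial 12S ribosomal RNA gene, at 15 mg/kg/day in 2 intraperitoneal injections a day for 8 days. The other casted mice and the uncasted mice received water on the same schedule. The groups are called uncasted, casted and casted with MOTS-c below. The libraries held between 19832 and 21755 genes with a TPM above 0, and their depth is unknown. No pair of libraries looked like a repeat deposit, since at most 1.34% of tested genes had equal values in any 2 libraries.

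The first comparison asks what 8 days of casting did to the muscle. Transcripts of muscle contraction and energy metabolism fell, and many transcripts of protein degradation and inflammation rose. The largest fall was that of Actc1, the cardiac alpha-actin gene (chromosome 2, 114047282 to 114053548), from 648 ± 159 (SD, n = 8) to 7.49 ± 3.91 scaled TPM, a log2 change of -6.33 ± 0.33 (SE, limma adjusted p = 1.51e-12). By log2 change, which understates low genes, the largest rise under the naming rule was that of Cpne2, a copine (chromosome 8, 94532990 to 94570531). It went from 4.55 ± 0.61 to 125.7 ± 33.3 scaled TPM, a log2 change of 4.49 ± 0.35 (limma adjusted p = 2.89e-10). The other leading rises were Aif1l (4.08), the metallothionein Mt2 (3.87), the stretch-responsive Ankrd1 (3.82), the collagen Col19a1 (3.52) and the ectodysplasin receptor Eda2r (3.52). The other leading falls were Nrep (-4.12), the lysine methyltransferase gene Mettl21c (-3.56), Amd1 (-3.33) and Amd2 (-2.85), near-identical copies of the gene for a polyamine synthesis enzyme, and Mybph (-3.02), which encodes a myosin-binding protein. In all, 4223 genes were higher and 4074 lower of 14690 tested, 452 and 414 of them by more than 2-fold. On the deposited TPM scale, 9132 were higher and 1091 lower, so that 89.3% of calls were rises in place of 50.9%.

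Many genes of protein breakdown rose with casting. Fbxo32 and Trim63, which encode the muscle ubiquitin ligases atrogin-1 and MuRF1, rose by 1.90 ± 0.27 (adjusted p = 1.79e-06) and 1.79 ± 0.31 (adjusted p = 2.62e-05), Fbxo32 from 105.4 ± 21.8 to 423 ± 174 scaled TPM. With only casted replicates 1 to 4 in the fit the rises were 1.39 and 1.34, and with only 5 to 8 they were 2.41 and 2.23. Of 22 atrophy ligases and FoxO targets, 11 rose and 4 fell, over all genes and adjusted over the list alone (20 and 0 on the deposited scale). Eif4ebp1 (2.19), which encodes a repressor of translation, and Sln (3.39), which encodes an inhibitor of the calcium pump, rose, as Mt2 did, and the ligase gene Stub1 fell (-0.46), though it was 0.05 higher on the deposited scale. All 32 proteasome subunit genes rose, on both scales, led by Psmd2 (1.68 ± 0.11), Psma7 (1.72) and Psmd4 (1.68). In the autophagy and lysosome list 18 of 24 genes rose, among them Map1lc3a (1.32), Atg7 (0.91) and Lamp1 (0.55), and only Ctsb, which overlaps Fdft1 on the other strand, fell (-0.19, but 0.33 higher on the deposited scale); adjusted over the list alone, 19 rose and 2 fell, and on the deposited scale 24 and 0. The 3 lists passed camera (adjusted p = 0.00928, 2.39e-17 and 2.3e-06) but not with an estimated correlation, which gave adjusted p = 0.495, 0.35 and 0.35.

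Genes of mitochondrial energy metabolism fell. Of 75 nuclear-encoded genes of oxidative phosphorylation 74 fell, with a median of -0.67, led by the complex I gene Ndufs1 (-1.08 ± 0.06), Cyc1 (-1.11) and Sdhb (-0.95), all with limma adjusted p of 7.19e-12 or lower. All 13 mitochondrially encoded subunit genes fell, with a mean of -1.05, among them mt-Co1 (-1.02), mt-Nd2 (-1.02) and mt-Nd6 (-1.67), which overlaps mt-Nd5 on the other strand by 14 bases. The 12S ribosomal RNA gene mt-Rnr1 (mitochondrial genome, 70 to 1024), as far as poly-A capture retained it, fell from 2522 ± 378 to 1128 ± 181 scaled TPM. Of 19 genes of the TCA cycle and pyruvate oxidation 16 fell, such as Cs (-0.78), Dlat (-0.82) and Sucla2 (-0.80); adjusted over the list alone, 17 fell. Of 29 genes of fatty acid uptake and oxidation 21 fell, such as Acaa2 (-1.36), Fabp3 (-1.48) and Hadhb (-0.82), and 2 rose, with Mlycd (0.30) as the stronger of them. Mlycd did not pass with only casted replicates 1 to 4 in the fit (0.06, limma adjusted p = 0.685), but did with only 5 to 8 (0.53, limma adjusted p = 4.47e-05). The counts of both oxidative phosphorylation lists and of the fatty acid list were identical when adjusted over the list alone. On the deposited scale the medians were -0.16, -0.49, -0.11 and 0.12, so that the direction of the fatty acid list turned, and 41, 13, 9 and 7 genes were lower and 4, 0, 5 and 12 higher. Ppargc1a, a coactivator that promotes mitochondrial gene expression, fell by 0.67 on the log2 scale (adjusted p = 0.00133), but did not pass on the deposited scale (-0.18, adjusted p = 0.323). The 4 lists passed camera (adjusted p between 7.24e-29 and 2.69e-06), but with an estimated correlation each had adjusted p = 0.35.

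Contractile and glycolytic transcripts fell as well. Of 18 glycolytic genes 15 fell, with Ldha (-1.81), Pgam2 (-1.74) and Pgk1 (-1.28) in the lead, and only Pfkfb3 rose (1.78), which encodes a regulatory kinase of glycolysis. Of 15 fast-fibre genes 13 fell, such as Casq1 (-2.26), Myl1 (-1.81) and Myoz1 (-1.28), whereas Myh1, the type 2X myosin heavy chain, rose by 0.45. Of 15 slow-fibre genes 10 fell, such as Myl3 (-2.02), Tnnt1 (-1.08) and Tnnc1 (-0.98), and 12 fell when adjusted over the list alone, which changed neither of the other counts. These lists passed camera at adjusted p = 6.77e-07, 5.26e-06 and 0.00276, and gave adjusted p = 0.35, 0.35 and 0.495 with an estimated correlation. Of these lists 11, 9 and 5 genes were lower and 3, 2 and 1 higher on the deposited scale. Myh1, which has the antisense transcript Myhas across it, was also higher on the deposited scale. It did not pass with only casted replicates 1 to 4 in the fit (0.25, limma adjusted p = 0.357), but did with only 5 to 8 (0.63, limma adjusted p = 0.00775).

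Inflammatory transcripts rose, and among the stress lists some did. Of 21 cytokine and NF-kB target genes 20 rose and none fell, by either adjustment, led by the NF-kB subunit genes Nfkb2 (3.23 ± 0.31) and Relb (2.07) and the chemokine gene Cxcl10 (2.59), which lies within Art3 on the other strand. Of 19 macrophage markers 13 rose and 1 fell, by either adjustment, with Cd68 (2.54), Ctss (1.10) and C1qb (0.65) rising and Folr2, a marker of resident macrophages, falling by 0.36 (0.05 higher on the deposited scale). Folr2 did not pass with only casted replicates 1 to 4 in the fit (-0.11, limma adjusted p = 0.629), but did with only 5 to 8 (-0.61, limma adjusted p = 0.00152). All 4 detected neutrophil and lymphocyte markers rose, too few for a list test. Of 14 p53 targets 9 rose and 1 fell (10 and 1 adjusted over the list alone); besides Eda2r, Gadd45a (3.22) and Bbc3 (1.11) rose, and Ccng1 fell (-1.15). Cdkn1a, an inhibitor of the cell cycle, rose by 1.72 ± 0.28. Of 14 glucocorticoid-responsive genes 8 rose and none fell, including Angptl4 (3.92 ± 0.89 to 10.3 ± 1.87 scaled TPM), and 6 of 13 endoplasmic reticulum stress genes rose, including Xbp1 (0.89), Hsp90b1 (0.67) and Calr (0.30), by either adjustment. The heat shock list (4 rose and 3 fell of 14, camera adjusted p = 0.975) and the integrated and mitochondrial stress response list (6 and 4 of 18, camera adjusted p = 0.606) were not called. Of 77 ribosomal protein genes 61 rose and none fell (63 adjusted over the list alone); Rpl3 rose by 1.92, Rpl10a by 0.72 and Rps25 by 0.69. Without scaling, 20 cytokine, 17 macrophage, 13 p53, 12 glucocorticoid, 13 reticulum stress, 77 ribosomal, 15 stress response and 7 heat shock genes were higher, and only 1, a p53 target, lower. The lists with rises passed camera at adjusted p between 1.76e-12 and 0.0252. With an estimated correlation adjusted p = 0.35 for the cytokine and p53 lists, 0.572 for macrophages and 0.495 for the glucocorticoid, reticulum stress and ribosomal lists.

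Extracellular matrix and vessel transcripts were lower after casting. Of 32 matrix genes 20 fell and 3 rose (21 and 3 adjusted over the list alone). The matrix median was -0.27 with only casted replicates 1 to 4 in the fit and -0.95 with only 5 to 8. Col1a1 fell by 2.22 ± 0.40 (limma adjusted p = 4.19e-05), from 89.3 ± 38.7 to 22.7 ± 21.1 scaled TPM. Its change was -1.37 with only casted replicates 1 to 4 (limma adjusted p = 0.0119) and -3.08 with only 5 to 8 (limma adjusted p = 3.37e-07). Col6a2 (-1.59), Col15a1 (-1.48) and Sparc (-1.19) fell too, whereas Lox, a collagen cross-linking enzyme, rose by 1.31. Of 12 endothelial markers 11 fell, such as Emcn (-0.73), Esam (-0.55) and Tie1 (-0.49), and Cldn5 rose (0.62), by either adjustment. Smooth muscle and pericyte markers fell in 7 of 10 cases (9 adjusted over the list alone), such as Rgs5 (-0.64), Lmod1 (-0.61) and Notch3 (-0.58), and Schwann cell and nerve markers in 6 of 10, by either adjustment, such as Pmp22 (-0.59) and Cnp (-0.50), which overlaps Dnajc7 on the other strand. Camera gave adjusted p = 0.00302, 0.00138, 0.00244 and 0.00937. With an estimated correlation these became adjusted p = 0.588, 0.382, 0.376 and 0.495. On the deposited scale these falls were mostly gone. The matrix list had 9 genes lower and 7 higher with a median of -0.14, and the other 3 lists had 2 lower each, 2, 0 and 0 higher, and medians of -0.03, -0.01 and 0.01. Esam, Tie1, Rgs5, Notch3, Pmp22 and Cnp did not pass there.

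Among the genes fixed in advance, the myostatin gene Mstn fell by 0.79 ± 0.12 (limma adjusted p = 3.48e-06), and the acetylcholine receptor gene Chrna1 and Myog rose by 1.43 and 0.76. Foxo1 (0.37 ± 0.23, adjusted p = 0.19), Pdk4 (0.29 ± 0.21, adjusted p = 0.253), Adipoq (0.16, adjusted p = 0.319), Plin1 (0.21, adjusted p = 0.259), Csnk2a1 (0.08, adjusted p = 0.169) and Prkaa2 (0.04, adjusted p = 0.726) did not pass. On the deposited scale all 6 passed, at 0.85, 0.80, 0.62, 0.60, 0.59 and 0.55 in that order (largest adjusted p = 0.00212). Fabp4 and Pparg were lower (-0.31 and -0.36), but 0.21 and 0.01 higher on the deposited scale, and Csnk2b was 0.17 higher. Of 16 adipocyte markers 1 rose and 6 fell, by either adjustment, and camera did not call the list (adjusted p = 0.416), while on the deposited scale 7 were higher and 1 lower.

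**Figure D1:**
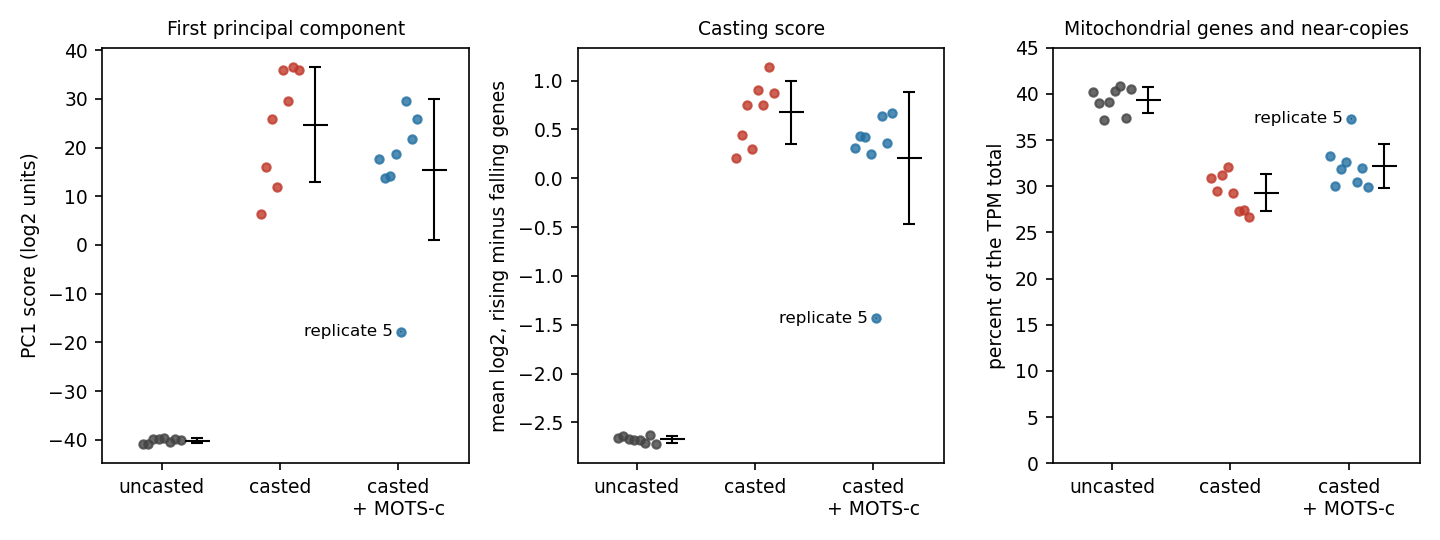
Each point is 1 library, for the first principal component of log2 values, the casting score (mean log2 value of 100 rising minus 100 falling genes, chosen from the uncasted and casted libraries) and the percent of the TPM total in mitochondrial genes and their nuclear near-copies; bars give mean ± SD of 8 libraries. Uncasted libraries lie close together, casted ones spread, and replicate 5 of the MOTS-c group lies between them with a score of -1.43.

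The first principal component held 50.05% of the variance and separated uncasted from casted libraries. Mitochondrial genes and their near-copies made up 39.3 ± 1.4% of the TPM total in uncasted, 29.3 ± 2.0% in casted and 32.2 ± 2.4% in MOTS-c libraries (SD, n = 8). The fall with casting had the smallest p that the exact permutation test can give (0.0001554, adjusted over 8 library measures 0.0001776), and the MOTS-c difference gave an exact permutation p = 0.01725 (adjusted 0.046). For the mitochondrially encoded genes alone the shares were 15.6 ± 1.25% in casted and 17.1 ± 1.61% in MOTS-c libraries (exact permutation p = 0.05346). For the near-copies alone, whose values are uncertain, they were 13.7 ± 0.83% and 15.1 ± 0.90% (exact permutation p = 0.004973, adjusted 0.03978). Against casted replicates 1 to 4 alone the difference in the share of mitochondrial genes and near-copies was 1.25 points (exact permutation p = 0.382), and against 5 to 8 alone 4.50 points (exact permutation p = 0.00606). Replicate 5 of the MOTS-c group stood apart, with a share of 37.3%.

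The second comparison asks what MOTS-c changed in casted muscle. In limma, 3 genes of 14690 passed, 2 higher and 1 lower, where 1986 had an unadjusted p under 0.05. Cyp2e1 (ENSMUSG00000025479, chromosome 7, 140763739 to 140774987), an ethanol- and fatty-acid-metabolizing cytochrome P450, was 20.8 ± 5.5 in casted and 41.3 ± 7.8 scaled TPM in MOTS-c libraries, a log2 change of 0.97 ± 0.16. Arxes2 (ENSMUSG00000048040, chromosome X, 135993824 to 135995355), an adipocyte gene with a close paralog, was near the floor of the filter, at 0.61 ± 0.13 and 1.27 ± 0.32 scaled TPM (0.48 ± 0.09). Gm45808 (ENSMUSG00000109926, chromosome 7, 45465984 to 45486811), a predicted coding gene that overlaps Bax by 915 and Dhdh by 15825 bases on the same strand, went from 11.9 ± 3.5 to 5.75 ± 1.56 (-0.91 ± 0.16), and its values are uncertain for that reason. All 3 had a limma adjusted p of 0.0417. Cyp2e1 was above the casted mean in 8 of 8 MOTS-c libraries and Arxes2 above the highest casted library in 8 of 8.

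These calls were close to the threshold, and the casted libraries were not alike. Within the casted group, replicates 1 to 4 and 5 to 8 differed in 100 genes, where the other 34 ways to divide the group gave at most 3. With only casted replicates 1 to 4 in the fit, MOTS-c gave 1 gene higher and 1 lower, and with only 5 to 8 it gave 698 and 705. Cyp2e1 was 0.85 and 1.10 higher in these fits (adjusted p = 0.402 and 0.00313), Arxes2 0.49 and 0.47 (0.402 and 0.0123), and Gm45808 changed by -0.57 and -1.24 (0.762 and 0.000169). Without replicate 5 of the MOTS-c group no gene passed in limma (1432 with an unadjusted p under 0.05), and Cyp2e1, at 0.97, had an adjusted p of 0.1. Across the 24 fits that each left out 1 library, the number of genes higher ranged from 0 to 41 and lower from 0 to 22, and without casted replicate 1 it was 63 in all. The other libraries that moved the count are named with the processing alternatives. On the deposited scale 3 genes were higher and 5 lower. No gene passed in limma with only the 2 groups fitted (1526 with an unadjusted p under 0.05), without a filter (2795), with a pseudocount of 0.1 (1955) or against a fold of at least 1.2 (97), whereas 18 passed with the replicate number as a block and 430 with a residual component as covariate. The 3-group fit shares 1 spread per gene over groups of unequal spread. The SD of the first principal component was 0.51 in uncasted, 11.9 in casted and 14.5 in MOTS-c libraries. The p-values of that fit for MOTS-c against casting may therefore be too small.

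**Figure D2:**
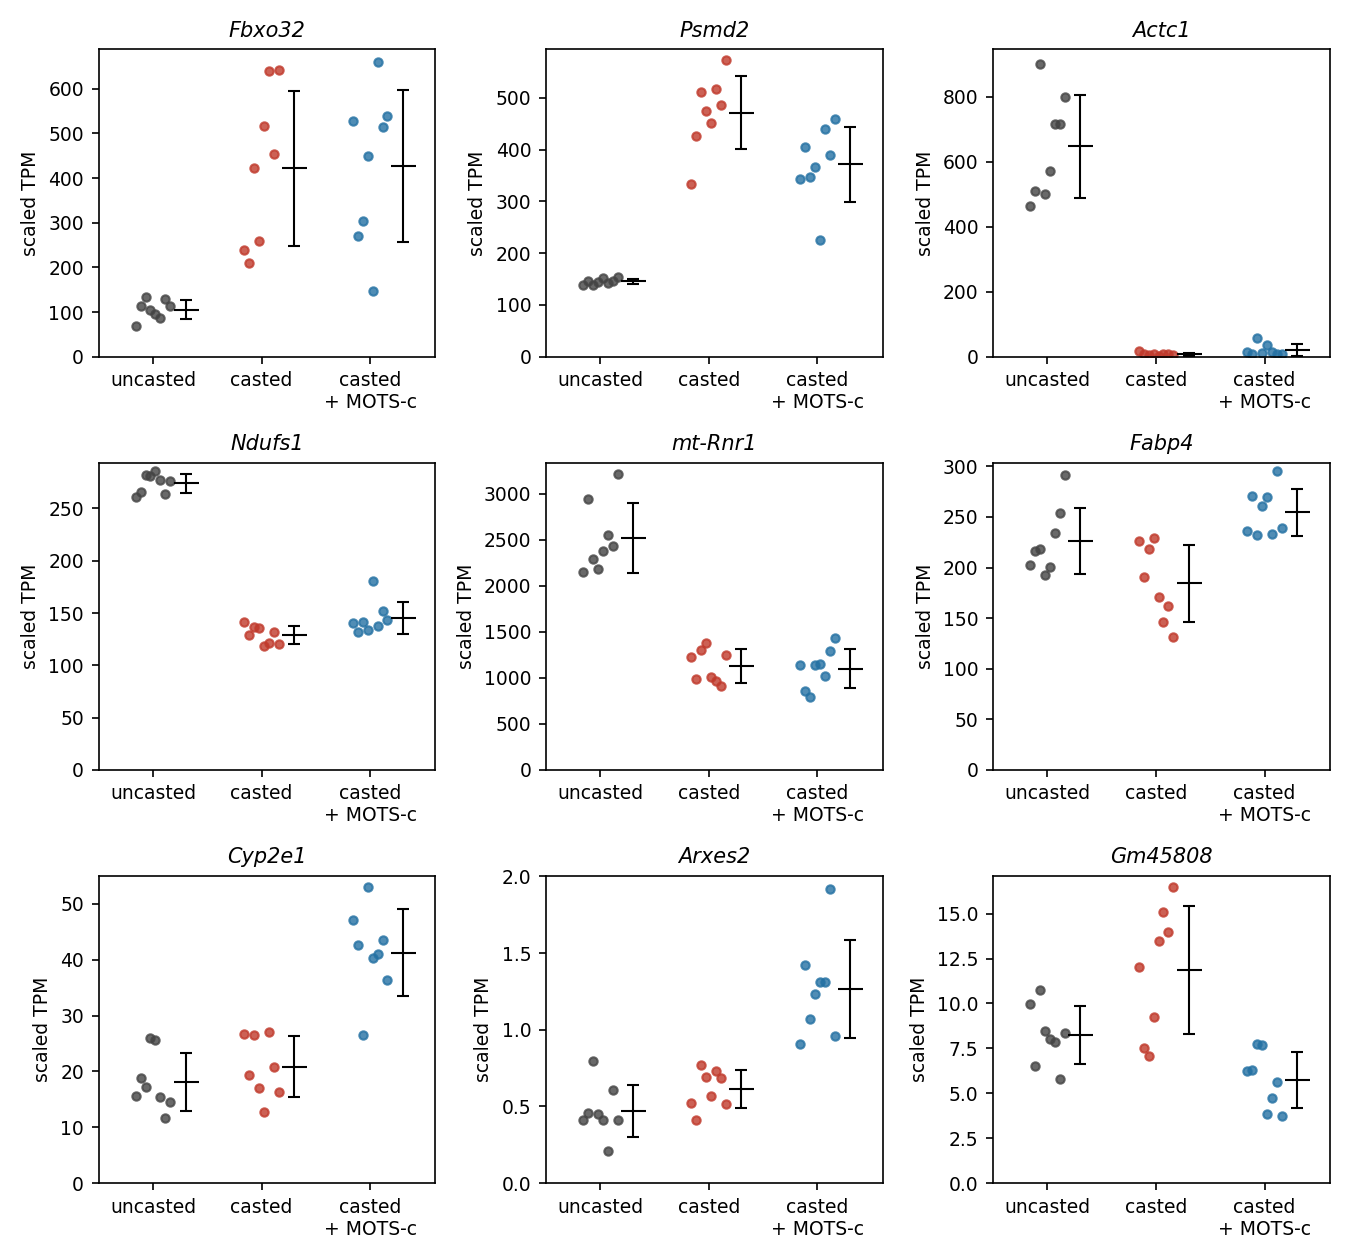
Scaled TPM of 9 genes per library (points) with mean ± SD of 8 libraries (bars), on linear axes from 0. Fbxo32 lies at similar levels in both casted groups (423 and 426), and Cyp2e1 is higher in the MOTS-c libraries (41.3 against 20.8).

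The atrophy genes showed no difference that passed with MOTS-c. Fbxo32 was 426 ± 170 against 423 ± 174 scaled TPM (log2 change 0.00 ± 0.27, limma adjusted p = 0.999) and Trim63 1061 ± 493 against 1043 ± 390 (-0.03 ± 0.31, adjusted p = 0.977). Against casted replicates 1 to 4 alone Fbxo32 was at 0.52 and against 5 to 8 alone at -0.51 (adjusted p = 0.995 and 0.255). The atrophy list as a whole was called higher by camera with the preset correlation in the former fit (adjusted p = 3.19e-05) and lower in the latter (adjusted p = 0.0246). Both fits kept all 8 MOTS-c libraries against 4 casted ones, so replicate numbers were not matched. The atrophy list mean (log2) was 5.07 to 5.62 in casted replicates 1 to 4 and 5.80 to 5.93 in 5 to 8. In MOTS-c libraries it was 5.36 to 5.89 in replicates 1 to 4, 5.07 in replicate 5 and 5.84 to 5.95 in 6 to 8. Foxo1 (0.34 ± 0.23) did not pass either. Values for Mstn (0.13), Ppargc1a (0.12), Myog (-0.02), Cdkn1a (0.18), Chrna1 (0.12), Plin1 (0.08), Pparg (0.08), Csnk2a1 (0.03), Csnk2b (-0.06), Prkaa2 (-0.07) and mt-Rnr1 (-0.04) had adjusted p of 0.626 or more. Pdk4, which encodes an inhibitory kinase of pyruvate oxidation, was 0.73 ± 0.21 higher (adjusted p = 0.179) and Col1a1 1.15 ± 0.40 higher (adjusted p = 0.245); Col1a1 was at 0.30 against casted replicates 1 to 4 (adjusted p = 0.995) and 2.01 against 5 to 8 (adjusted p = 0.0025).

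Camera called 22 of 36 lists with MOTS-c, 16 higher and 6 lower, while no member of any list passed over all genes. Adjusted over the list alone, 1 member each of the atrophy and glucocorticoid lists, which camera did not call, was higher. With an estimated correlation none passed (smallest adjusted p = 0.259), and fry called only the adipocyte list. With only casted replicates 1 to 4 camera called 13 lists, 7 of them higher, and with only 5 to 8 it called 18, 13 of them higher. Adipocyte markers had a median of 0.31 (camera adjusted p = 7.22e-07, fry adjusted p = 0.0277, adjusted p = 0.259 with an estimated correlation), and 7 of 16 were higher adjusted over the list alone. Fabp4 (0.49 ± 0.11), Adipoq (0.60 ± 0.14) and Cidec (0.59 ± 0.16) led, with limma adjusted p of 0.0826, 0.0826 and 0.141 over all genes. Fabp4, also expressed by capillary endothelium, was above the highest casted library in 8 of 8 MOTS-c libraries. The mean over the list differed by 0.28 (exact permutation p = 0.005905, adjusted over 37 lists 0.1073). The median was 0.19 against casted replicates 1 to 4 and 0.31 against 5 to 8, and Fabp4 was at 0.23 and 0.75.

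Lists of other non-muscle cells were also higher. Macrophage markers had a median of 0.44, with 10 of 19 higher adjusted over the list alone, led by Cd163 (0.62, limma adjusted p = 0.0778), C1qa (0.54) and Folr2 (0.56). The median was 0.43 for matrix genes (12 of 32 by list alone; Eln 0.51, Fn1 0.88, Bgn 0.66), 0.27 for Schwann cell markers (5 of 10; Pmp22 0.41, Prx 0.34) and 0.16 for fibro-adipogenic progenitor markers (2 of 13; Pi16 0.80, Mfap5 0.59, Lum 0.47). It was 0.18 for smooth muscle (1 of 10; Tagln 0.44, Myh11 0.27, Pdgfrb 0.22), 0.14 for endothelium (0 of 12; Vwf 0.26, Cldn5 0.44, Pecam1 0.18), 0.16 for erythroid genes (0 of 5; Hba-a2 0.26, Hba-a1 0.16, Hbb-bs 0.16) and 0.16 for proliferation genes (1 of 8; Ccna2 0.48, Tpx2 0.19, Top2a 0.27). Camera adjusted p values ran from 7.27e-12 for the matrix to 0.029 for erythroid genes. With an estimated correlation adjusted p = 0.361 for the macrophage and Schwann lists, 0.375 for the matrix, progenitor, smooth muscle, endothelial and proliferation lists, and 0.52 for the erythroid list. For most of these lists, the matrix above all, the difference was larger against casted replicates 5 to 8, in fits that kept all 8 MOTS-c libraries. Against casted replicates 1 to 4 and against 5 to 8 the median was 0.22 and 0.68 for macrophages, 0.07 and 0.80 for the matrix, 0.25 and 0.30 for Schwann cells, 0.06 and 0.31 for progenitors, 0.13 and 0.33 for smooth muscle, 0.04 and 0.26 for endothelium, 0.19 and 0.20 for erythroid and 0.14 and 0.25 for proliferation genes. Replicate 5 of the MOTS-c group, which stood apart, was part of these values, and without it camera called 14 lists. The list mean difference without it was 0.46 for macrophages (0.41 with it), 0.44 for the matrix (0.45), 0.22 for progenitors (0.23) and 0.20 for proliferation (0.18). It was lower for Schwann cells (0.21, from 0.28), smooth muscle (0.15, from 0.19), endothelium (0.14, from 0.17) and erythroid genes (0.14, from 0.17).

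Muscle metabolism lists moved little, and mostly against casted replicates 5 to 8. Medians were 0.10 for nuclear-encoded oxidative phosphorylation (Atp5k 0.58, Cox6b1 0.28, Ndufs1 0.16), 0.18 for the mitochondrially encoded list (mt-Nd6 0.86 ± 0.19, limma adjusted p = 0.0826; mt-Atp8 0.91, which overlaps mt-Atp6 by 43 bases; mt-Nd4l 0.44), 0.17 for glycolysis (Pfkfb1 0.44, Ldha 0.38, Phkg1 0.33) and 0.12 and 0.14 for fast and slow fibres (Myoz1 0.30, Casq1 0.43, Myl1 0.26; Myh7b 0.30, Mybpc1 0.13, Tnnt1 0.26). The TCA cycle list (Mdh2 0.17, Sucla2 0.11, Pdha1 0.10) and the fatty acid list (Lpl 0.33, Pdk4 0.73, Fabp3 0.36) both had a median of 0.04, which was -0.04 on the deposited scale. Adjusted over the list alone, 3 fatty acid and 2 mitochondrially encoded genes were higher. Camera called these 7 lists higher (adjusted p between 1.15e-07 and 0.047), but with an estimated correlation adjusted p was between 0.484 and 0.588. Against casted replicates 1 to 4 and against 5 to 8 the medians were -0.04 and 0.23 for nuclear-encoded and 0.05 and 0.32 for mitochondrially encoded oxidative phosphorylation, and 0.06 and 0.31 for glycolysis. They were -0.01 and 0.24 for fast fibres, -0.04 and 0.33 for slow fibres, 0.05 and 0.07 for the TCA cycle, and 0.12 and -0.01 for fatty acids. Among the leading members, mt-Atp8 was at 0.07 and 1.75, mt-Nd4l at -0.13 and 1.02, mt-Nd6 at 0.32 and 1.41, Atp5k at 0.00 and 1.17 and Cox6b1 at 0.10 and 0.47. Without MOTS-c replicate 5 the list mean difference was 0.07 for nuclear-encoded (0.11 with it) and 0.17 for mitochondrially encoded oxidative phosphorylation (0.25). It was 0.07 for glycolysis (0.18), 0.06 for fast fibres (0.15) and 0.01 for the TCA cycle (0.05). Slow fibres, at 0.15 (0.14), and fatty acids, at 0.10 (0.10), were little changed.

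The 6 lists called lower were proteasome subunits (median -0.22; Psmd2 -0.35, Psmb5 -0.31, Psmd6 -0.24), autophagy (-0.08; Atg5 -0.17, Atg7 -0.19, Gaa -0.27) and reticulum stress (-0.13; Hspa5 -0.25, Dnajc3 -0.16, Xbp1 -0.27). The others were ribosomal proteins (-0.06; Rps7 -0.19, Rpl3 -0.38), circadian clock genes (-0.14; Ciart -0.62 ± 0.12, Nr1d2 -0.14, Tef -0.15) and immediate early genes (-0.23; Jund -0.28, Junb -0.62, Fosb -0.21). Camera adjusted p was 9.8e-12 for the proteasome and at most 0.0112 for the others. With an estimated correlation adjusted p = 0.402, 0.553, 0.52, 0.798, 0.361 and 0.375, in the same order. Only Ciart, a repressor of the clock, passed adjusted over a list alone, and its limma adjusted p over all genes was 0.0672. Against casted replicates 1 to 4 Ciart was at -0.89 (adjusted p = 0.00211) and against 5 to 8 at -0.33 (adjusted p = 0.0679). The list medians against these sets were -0.16 and -0.27 for the proteasome, -0.02 and -0.17 for autophagy, -0.07 and -0.11 for reticulum stress, -0.10 and 0.01 for ribosomal proteins, -0.07 and -0.08 for the clock, and -0.21 and -0.20 for immediate early genes. Without MOTS-c replicate 5 the list mean difference was -0.14 for the proteasome (-0.23 with it), -0.04 for autophagy (-0.10) and -0.07 for reticulum stress (-0.12). It was -0.01 for ribosomal proteins (-0.04), -0.15 for the clock (-0.14) and -0.23 for immediate early genes (-0.23).

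**Figure D3:**
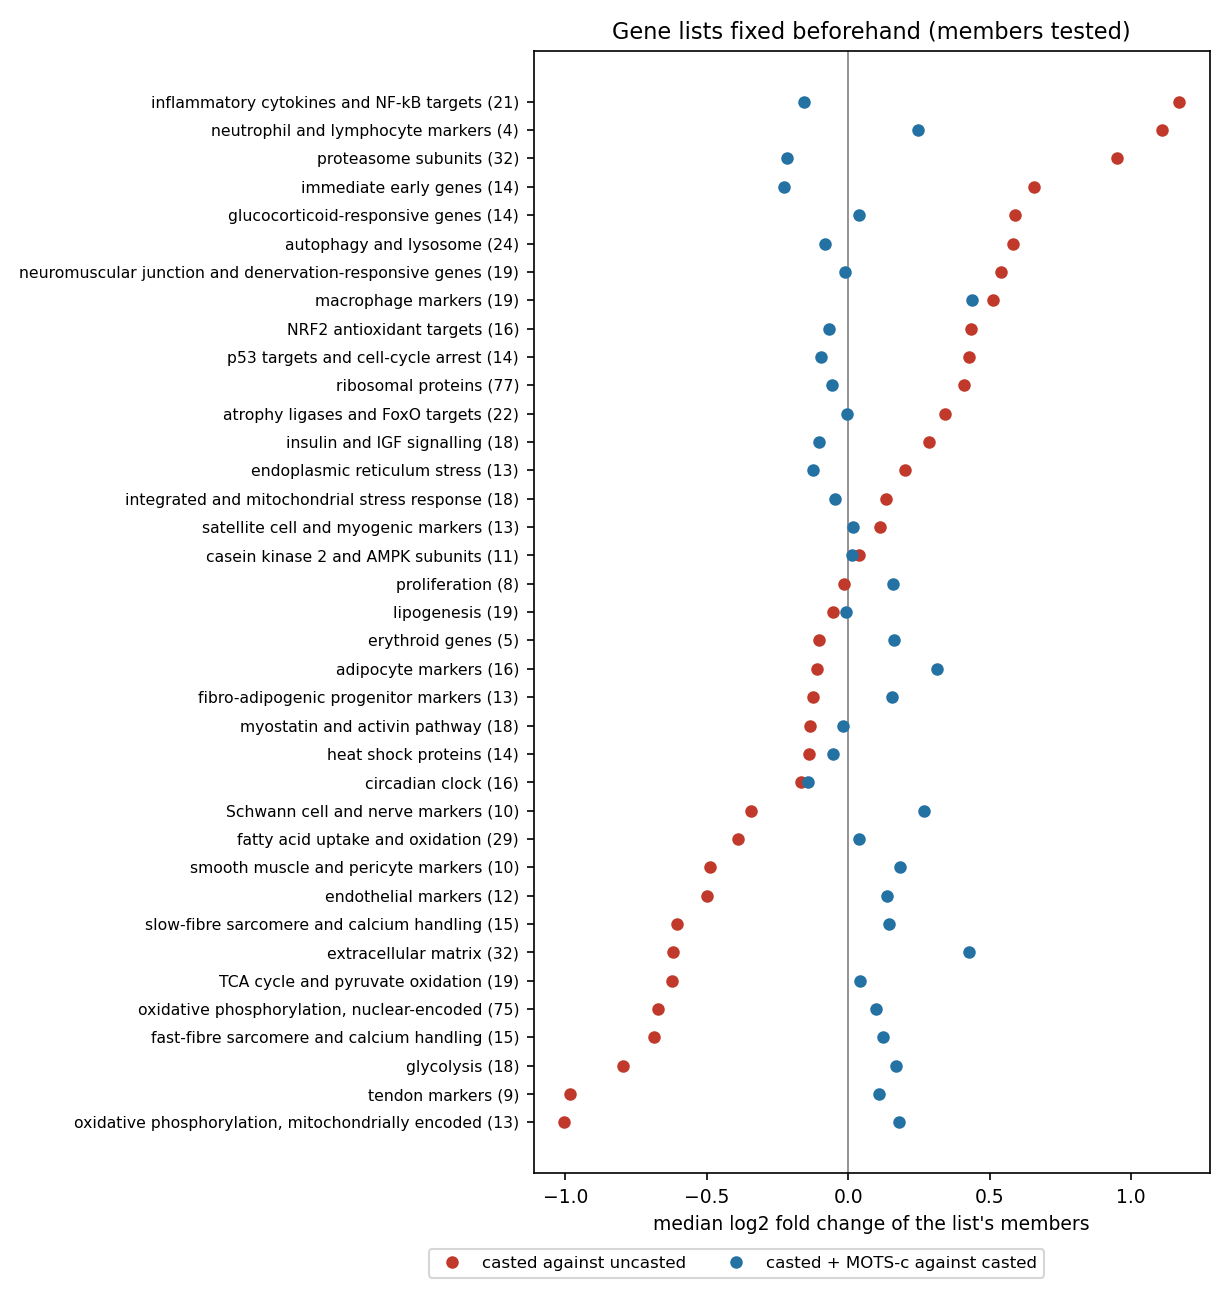
Median log2 fold change of the members of each of the 37 gene lists (number of members tested in brackets) for casting (red) and for MOTS-c in casted mice (blue), on scaled TPM. Proteasome subunits have medians of 0.95 and -0.22, and macrophage markers 0.51 and 0.44. On the deposited TPM scale the casting medians of the fatty acid oxidation, Schwann cell, lipogenesis, adipocyte, progenitor, erythroid, proliferation, heat shock, myostatin and clock lists turn positive, and the MOTS-c medians of the TCA cycle, fatty acid oxidation, satellite cell, glucocorticoid and casein kinase lists turn negative.

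The casting score tested whether the casting pattern as a whole was weaker with MOTS-c. With genes chosen from casted replicates 1 to 4, the score was -0.35 ± 0.77 in 8 MOTS-c libraries and 0.46 ± 0.28 in casted replicates 5 to 8, against -3.36 ± 0.04 in the uncasted libraries. The difference of -0.81 had an exact permutation p of 0.0404. With the sets of casted replicates exchanged it was -0.06 (exact permutation p = 0.927), so the result depended on which casted libraries chose the genes and which were the reference, 2 choices that the exchange changes together. With genes chosen from all casted libraries, casted replicates 1 to 4 scored 0.21 to 0.75 and replicates 5 to 8 scored 0.75 to 1.14. Over all 70 choices of 4 casted libraries the difference was below 0 in 70 and averaged -0.45, with a permutation p under 0.05 in 2, and the planned choice gave the lowest of the 70. Without MOTS-c replicate 5 the planned difference was -0.54 (exact permutation p = 0.00606), but with the sets exchanged it was 0.21 (exact permutation p = 0.361). The mean over 70 choices was then -0.20, with 63 below 0 and a permutation p under 0.05 in 7.

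Across 14690 genes, which are not independent replicates, the log2 changes of casting and of MOTS-c had a Pearson r of -0.51 and a covariance of -0.0488. The shared casted libraries give a negative value with no effect at all, and 100 simulations gave a mean r of -0.50 (range -0.76 to -0.16) and a mean covariance of -0.00973 (range -0.0241 to -0.00308). With the casted libraries divided, r was -0.41 with replicates 1 to 4 in the casting comparison and 0.02 with replicates 5 to 8, both within the range of divided libraries in simulations with no effect (-0.55 to 0.33), and it averaged -0.35 over all 70 divisions. In 100 simulations that kept the casting effect and had no MOTS-c effect, 2 had a covariance as low as the observed one and 6 an r as low. All these simulations shuffled deviations over the 24 libraries, so the tighter uncasted libraries stood in for casted ones. The simulated ranges may thus be too narrow, and the simulations cannot decide whether MOTS-c acted against casting.

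The third comparison set casted muscle with MOTS-c against uncasted muscle. In limma 3817 genes were higher and 3628 lower (8808 and 1019 on the deposited scale). The log2 changes were 1.90 for Fbxo32, 1.76 for Trim63, 3.97 for Cpne2, 1.32 for Psmd2, -0.92 for Ndufs1 and -5.32 for Actc1. All 32 proteasome genes were higher and 74 of 75 nuclear-encoded oxidative phosphorylation genes lower, on the scaled values, by either adjustment (32 higher, and 39 lower with 4 higher, on the deposited scale). Macrophage markers were higher in 17 of 19 cases, and of 16 adipocyte markers 6 were higher, among them Adipoq (0.76, limma adjusted p = 5.37e-05) and Cidec (0.95, limma adjusted p = 1.88e-05), and 4 lower, a list that camera did not call (adjusted p = 0.44). Matrix genes were lower in 9 and higher in 6 of 32 cases, but lower in 3 and higher in 10 on the deposited scale. Of 36 lists camera called 17, 8 higher and 9 lower, none with an estimated correlation (smallest adjusted p = 0.38). Whether these values differ from those of casting alone is the second comparison, in which none of these genes passed.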

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

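The tests of composition by mitochondrial genes, of a wrong label, of macrophage markers and of the share of non-muscle tissue were chosen after the results were seen, as were the residual component as covariate and the splits in the 3-group fit and within groups; the other tests in this part were set before their results. A gap between the extreme library and its nearest neighbour, divided by the range of the 8 libraries of a group, was compared with Dixon's 95% critical value for 8 samples, for library measures and every named gene. It was exceeded in 43 of 453 combinations of measure and group, where chance alone gives about 1 in 20, and 31 of the 43 were MOTS-c replicate 5. For that library the ratio was 0.804 for the casting score, 0.665 for the first principal component, 0.542 for the mitochondrial share and 0.622 for the share of the 10 most abundant genes. Among genes that rise with casting, it was 0.76 for Cpne2, 0.617 for Aif1l, 0.59 for Col19a1, 0.689 for Eda2r, 0.731 for Relb, 0.745 for Nfkb2, 0.759 for Gadd45a, 0.537 for Bbc3, 0.786 for Rpl3, 0.55 for Chrna1, 0.589 for Psmd2 and 0.578 for Psma7. Among genes that fall, it was 0.598 for Amd1, 0.678 for Amd2, 0.552 for Ndufs1, 0.559 for Dlat, 0.536 for Pgk1, 0.528 for Pgam2, 0.557 for Ldha, 0.669 for Casq1, 0.76 for Cnp and 0.68 for Ccng1. It was 0.61 for Gaa, 0.574 for Atp5k, 0.568 for mt-Atp8, 0.556 for Pdha1 and 0.544 for Phkg1, named for the MOTS-c lists. These values are not independent of each other. The other 12 were Ankrd1 (0.648), Myl1 (0.535) and Dnajc3 (0.588) in uncasted replicate 8, Hspa5 (0.562) and Fosb (0.574) in uncasted replicate 2, Atg7 in uncasted replicate 4 (0.577) and Ciart in uncasted replicate 1 (0.767), Mybph in casted replicate 2 (0.555) and Cdkn1a in casted replicate 1 (0.624), and Myh1 (0.593) and Dnajc3 (0.53) in MOTS-c replicate 6 and Bgn (0.55) in MOTS-c replicate 8.

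MOTS-c replicate 5 lay between the casted and uncasted libraries, with a casting score of -1.43 where the other 15 casted libraries ranged from 0.21 to 1.14. A wrong label on an uncasted mouse is argued against by its score, which was 1.197 above the highest uncasted library, where the 8 uncasted scores spanned 0.0942. A mixture of RNA from casted and uncasted muscle would move rising and falling genes by the same fraction of the casting change. The fractions were 0.15 for rising and 0.63 for falling genes, a difference of -0.4843, where the other casted libraries averaged -0.08 with an SD of 0.13. What stays open is a milder or shorter effect of the cast in this mouse, for which the design has no group, so no biological explanation was tested.

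On the deposited TPM scale 89.3% of the genes called with casting were higher. A fall of the mitochondrial share from 39.3% to 29.3% may account for part of this, since removing these genes and rescaling left a median log2 change of 0.2478 ± 0.0292 (SE) of the original 0.39. Removing the 100 most abundant genes, 21 of them mitochondrial or near-copies, whose share went from 68.6% to 55.1%, left a median of 0.0134 ± 0.0226. This is in line with a composition effect of abundant muscle transcripts. TPM cannot show whether the amount of RNA per cell changed, so a biological change in total RNA stays open.

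Macrophage and other non-muscle lists were higher with MOTS-c by camera, although no member passed over all genes and no list passed with an estimated correlation (adjusted p = 0.361 for macrophages). A weaker casting response in the MOTS-c group stays open, because the macrophage list, which rose with casting and was higher again with MOTS-c, was picked after the results and did not pass over the 37 lists (list mean 0.41, adjusted exact permutation p = 0.2616). Of its 19 members 17 were above 0 with casting and 18 with MOTS-c, where Cd68 was the exception (-0.17). A larger share of non-muscle tissue in the MOTS-c pieces cannot be told apart from a change in these cells, because the macrophage minus endothelial difference of 0.25 had an exact permutation p of 0.1444. An effect of MOTS-c on these cells also stays open. The matrix median was 0.80 against casted replicates 5 to 8 and 0.07 against 1 to 4. That of Schwann cell markers was 0.30 and 0.25. These fits set all 8 MOTS-c libraries against 4 casted ones, so replicate numbers were not matched. The matrix list mean (log2) was 3.61 to 4.50 in casted replicates 1 to 4 and 3.07 to 3.72 in 5 to 8. In MOTS-c libraries of the same numbers it was 4.20 to 4.68 and 3.49 to 4.28, and in uncasted libraries 4.22 to 4.51 and 3.90 to 4.28. The ranges were thus lower at the higher numbers in all 3 groups, though they overlapped.

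For casting, 8346 genes passed in the 2-group fit, and 1 of 100 splits, the real one, gave as many (highest other 6189), so chance is excluded. For MOTS-c against uncasted mice 7378 passed, reached by 1 of 100 splits (highest other 1). For MOTS-c against casting, the 2-group fit in limma called 0 genes (1526 with an unadjusted p under 0.05), a number that all 100 splits reach by definition (highest other 9), which says nothing about chance. In the 3-group fit 3 genes passed, 5 of 100 splits gave as many and the highest other gave 283, so chance is not excluded for these 3 genes. With the residual component as covariate 169 genes passed in the 2-group fit, but 9 of 100 splits gave as many and the highest gave 937. Splits with several times the real count, in the 3-group fit and with this covariate, point to a structure of the libraries other than their groups, the cause of which was not tested. With MOTS-c and all libraries, 1 of 100 splits, the real one, gave 22 lists called by camera in the 3-group fit (highest other 21). In the 2-group fit 3 splits gave 20 or more (highest other 21). Few splits reached the real number, but the margin was small and the 3-group splits were chosen after the results, so chance is not firmly excluded. The median of the other splits was 12 lists in both fits, so that camera called many of the 36 lists in arbitrary groupings too. Without MOTS-c replicate 5 chance is not excluded, since 39 of 100 splits reached the real 14 (highest other 20). The number of lists did not exclude chance for casting, where 7 of 100 splits reached the real 21 (highest other 24), nor for MOTS-c against uncasted mice, where 26 reached the real 17 (highest other 24).

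Replicates 1 to 4 and 5 to 8 of the casted group differed in 100 genes in limma, which 1 of the 35 splits of these 8 libraries, this one, reached (highest other 3). A share of 1 in 35 is the smallest that this test can give. The test was chosen after the results and run in 3 groups, so chance is not firmly excluded. In the uncasted group 4 genes differed, reached by 2 of 35 splits (highest other 4), so chance is not excluded. In the MOTS-c group 0 differed, which all 35 splits reach by definition (highest other 16). Genes with an unadjusted p under 0.05 numbered 3215 in the casted group (highest other split 2562), 1454 in the uncasted group (1202) and 903 in the MOTS-c group (2091). By that count this division exceeded all others in the casted and in the uncasted group, but not in the MOTS-c group. The labels give no batch or day, so what sets these casted replicates apart was not tested, and MOTS-c differences that appear against only 4 of the casted libraries cannot be put down to MOTS-c from these data.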

How the results depend on the processing

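The pseudocount of 0.1, the residual component, the removal of mitochondrial genes, the averages over 70 choices, the exchanged replicates without MOTS-c replicate 5, fits with only 4 casted replicates, the mitochondrially encoded share alone, list tests on the deposited TPM, and leaving out libraries in list tests and in the mitochondrial share were chosen after seeing the data. With casting, counts kept within 1.5 times with median of ratios scaling, no filter, a filter of TPM 1, only 2 groups fitted, the replicate block, a pseudocount of 0.1 or the residual component. With only casted replicates 1 to 4 they were 3037 higher and 2915 lower, and with only 5 to 8 they were 4109 and 4160. With 1 library left out they were 4018 to 4265 higher and 3864 to 4144 lower. The deposited TPM gave 9132 higher and 1091 lower, removing mitochondrial genes 7210 and 1931, and a test against a fold of 1.2 gave 1788 and 1717. For MOTS-c against uncasted mice these were 8808 and 1019, 7036 and 1591, and 1279 and 1292, and 3614 to 3981 and 3422 to 3743 with 1 library left out. By construction the fold test is stricter; the scaling effect follows from shares of a total. Of 89 named genes past the threshold with casting, 72 stayed past it in the same direction under every alternative, and the exceptions were Calr, Cldn5, Cnp, Csnk2b, Ctsb, Esam, Fabp4, Folr2, Mlycd, Myh1, Notch3, Pmp22, Pparg, Ppargc1a, Rgs5, Stub1 and Tie1. On the deposited TPM 5 changed direction: Stub1 0.0459, Ctsb 0.328, Folr2 0.0484, Fabp4 0.206 and Pparg 0.00606, and Ctsb was 0.109 without mitochondrial genes.

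With MOTS-c in casted mice, 2 genes were higher and 1 lower. No gene passed in limma without a filter (2795 with an unadjusted p under 0.05), with only 2 groups fitted (1526), with a fold of 1.2 (97) or with a pseudocount of 0.1 (1955). On the deposited TPM 3 were higher and 5 lower, and with the residual component 174 and 256; the cause was not tested. With only casted replicates 1 to 4, 1 was higher and 1 lower, and with only 5 to 8, 698 and 705. With 1 library left out, 0 to 41 were higher and 0 to 22 lower. No gene passed without uncasted replicate 8, casted replicate 5, 7 or 8, or MOTS-c replicate 2, 4, 5, 6 or 7; 63 passed without casted replicate 1, 26 without MOTS-c replicate 8, 9 without casted replicate 2 and 7 without casted replicate 4. One gene passed without uncasted replicate 4 or 5, casted replicate 6 or MOTS-c replicate 1. The adjusted p of Cyp2e1 ran from 0.00313 to 1, past the threshold in 21 of 36 alternatives, that of Arxes2 in 19 and that of Gm45808 in 15.

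With the replicate number as a block, 13 genes were higher and 5 lower with MOTS-c, and no other count moved by over 1.5 times. The labels do not say that a number is shared by mice, and the numbers were not treated as pairs, since same-number correlations of deviations were over 0.1 in only 1, 3 and 2 of 8 pairs for uncasted with casted, uncasted with MOTS-c and casted with MOTS-c libraries (mean 0.05, 0.09 and 0.00). Of 16 libraries, 3, 7 and 4 correlated best with their own number, where chance alone gives about 1 in 8. The mean correlation was above that of shuffled numbers for the pairs with uncasted libraries (one-sided permutation p = 0.0408, 6e-04 and 0.484). Some numbers thus appear to share something, most clearly in uncasted with MOTS-c libraries. What they share was not tested, and the main fit takes no account of it.

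The casting score difference of -0.81 became -0.0614 with replicates exchanged, 0.213 with replicates exchanged and no MOTS-c replicate 5 (exact permutation p = 0.361), -0.91 with 50 genes per direction (exact permutation p = 0.0525) and -0.445 as the mean over 70 choices (-0.196 without MOTS-c replicate 5). With a library left out it ranged from -0.91 to -0.545 (permutation p 0.00606 to 0.2), and leaving out casted replicate 5, 6, 7 or 8 ended the call (permutation p = 0.139, 0.0909, 0.2 and 0.139), with 3 reference libraries. The correlation of fold changes was 0.0183 with replicates 5 to 8 in the casting comparison, and -0.584 to -0.322 with a library left out. The lists called went from 20, 22 and 17 to 0 in each comparison with an estimated correlation, to 28, 1 and 23 with fry, to 13 with MOTS-c with only casted replicates 1 to 4 (18 with only 5 to 8), and to 14 with MOTS-c without its replicate 5, with ranges of 20 to 22, 14 to 22 and 16 to 18 with 1 library left out. The MOTS-c difference in mitochondrial share kept an exact permutation p under 0.05 without any single library. It lost it for the mitochondrially encoded genes alone (exact permutation p = 0.05346) and with only casted replicates 1 to 4 (exact permutation p = 0.382). With only casted replicates 1 to 4, the nuclear-encoded oxidative phosphorylation list turned to lower with MOTS-c by camera with the preset correlation (adjusted p = 0.0251). Planned count models, voom and surrogate variables were not run, for lack of counts. Depth is unknown, so no detection limit can be given for low genes such as Arxes2.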

Other observations

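The test of clock phase was set before its result was seen. On the scaled values, several lists fixed beforehand moved in both directions with casting. Of 19 neuromuscular junction and denervation-responsive genes 11 rose and 8 fell, by either adjustment, and camera did not call the list (adjusted p = 0.192). Satellite cell and myogenic markers rose in 4 and fell in 3 of 13 cases, and NRF2 antioxidant targets rose in 10 and fell in 2 of 16 (camera adjusted p = 0.321 and 0.056). Insulin and IGF signalling genes rose in 11 and fell in 5 of 18, and myostatin and activin pathway genes rose in 6 and fell in 6 of 18 (camera adjusted p = 0.217 and 0.961). Immediate early genes rose in 8 and fell in 3 of 14 (9 and 3 adjusted over the list alone, camera adjusted p = 0.129). In tendon markers 5 of 9 fell and none rose (0.0752), in fibro-adipogenic progenitor markers 5 of 13 fell and 1 rose (0.455), and in lipogenesis genes 6 of 19 fell and 3 rose (0.455). Stress response genes rose in 6 and fell in 4 of 18 cases (0.606), heat shock genes rose in 4 and fell in 3 of 14 (0.975), and casein kinase 2 and AMPK genes rose in 3 and fell in 4 of 11 (0.827). Clock genes rose in 5 and fell in 7 of 16 cases (5 and 8 adjusted over the list alone, 0.481), proliferation genes rose in 1 and fell in 1 of 8 (0.961), and no erythroid gene passed of 5 (0.619). On the deposited scale rises outnumbered falls in all of these lists but tendon (1 higher and 2 lower). The counts there were 11 and 4 for the neuromuscular junction, 8 and 0 for satellite cells, 14 and 2 for NRF2, 13 and 2 for insulin and IGF, 9 and 2 for myostatin and 11 and 2 for immediate early genes. They were 8 and 1 for progenitors, 13 and 2 for lipogenesis, 15 and 0 for the stress response, 7 and 0 for heat shock, 8 and 0 for casein kinase 2, 10 and 3 for the clock, 2 and 0 for proliferation and 4 and 0 for erythroid genes. The casein kinase 2 list had a median of 0.04 with casting where its mean was -0.07 and camera gave a downward direction, and the heat shock list a median of -0.14 with a mean of 0.13.

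With MOTS-c no member of the lists that camera left uncalled passed over all genes. Camera adjusted p was 0.0554 for cytokines and NF-kB targets (median -0.16), 0.0902 for insulin and IGF signalling, 0.117 for the p53 and for the NRF2 list, 0.228 for tendon, 0.289 for glucocorticoid-responsive genes and 0.319 for satellite cell markers. It was 0.426 for heat shock, 0.654 for the stress response, 0.829 for the neuromuscular junction, 0.85 for casein kinase 2 and AMPK, 0.871 for myostatin, 0.88 for atrophy and 0.93 for lipogenesis. The 4 neutrophil and lymphocyte markers tested had a median of 0.25, with no member past the threshold by either adjustment.

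Clock genes were lower with MOTS-c as a list by camera, but not with an estimated correlation (adjusted p = 0.361), and the list mean had an adjusted exact permutation p of 0.1073. Ciart was below the lowest casted library in 7 of 8 MOTS-c libraries, and the list mean was below the casted mean in all 8. A shift in the time of day at sampling may give such a difference, in which case genes that peak with Arntl would move against those that peak with Dbp. The 2 genes with Arntl differed by 0.05 and the 7 with Dbp by -0.22 (exact permutation p = 0.7674 and 0.01709). The difference between the sets was 0.26 with an exact permutation p of 0.2368, so the test leaves the hypothesis open. Casting itself moved the sets apart by 1.152, with the smallest p the test can give (0.0001554). Sampling times are not given in the sources used here.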
